A study of Danio rerio with 4 samples.

How the data were processed

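Single-cell transcriptomes were measured in zebrafish embryos at 48 hours post-fertilization that carried Tg(kdrl:mCherry), a transgene in which the promoter of the endothelial receptor gene kdrl drives the red fluorescent protein mCherry. The 4 libraries fall into a control group and a group injected with a morpholino, an antisense oligomer, against prdx1, which encodes the antioxidant enzyme peroxiredoxin 1. Each group had 2 libraries. The labels give neither the treatment of the control embryos nor whether the morpholino blocks translation or splicing. Per the labels' protocols, pooled embryos were dissociated with Liberase, fluorescent cells were collected by flow cytometry, and droplet libraries were made with 10x Genomics 3′ chemistry version 3.1 and sequenced on an Illumina NovaSeq. The sample labels name mCherry as the sorted reporter, whereas a sentence of the protocol names GFP. Per the labels, the cells of each condition were split over 2 lanes as technical replicates, so each group is taken as 1 cell suspension. P-values therefore measure the spread between lanes and not the spread between clutches, injections or sorts.

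The deposited files hold raw UMI counts per gene and cell barcode in a matrix for each library, as whole numbers with no normalization by the authors. UMIs are molecular tags that count captured transcripts once. Per the file headers, the counts were made with Cell Ranger 7.1.0. The submitters' processing notes list Cell Ranger 2.1, R 4.3.0, Seurat 4.3.0.1 and the genome build GRCz11, and the difference in Cell Ranger version was not resolved here. The matrices list 25108 genes, and gene names are those in the files, with the gene identifier added where several identifiers share a symbol. The reference tables at hand describe another genome build, so no coordinates are given. The lowest barcode held 500 or 501 UMIs in every library. The 11345 barcodes divided into 4226 in control 1, 1140 in control 2, 3428 in morphant 1 and 2551 in morphant 2.

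The tests, cell filters, marker lists, gene lists and the rule for naming genes were fixed before the data were examined. Cells were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes. Doublets were scored in each library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.05. Its automatic threshold marked 0 to 0.0949% of cells per library, below the 0.5% fixed as the lowest credible share, and the fallback fixed with it removed cells in the top 5% of scores. This took 478 cells and left 9704. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with library as batch, and 30 principal components with 15 neighbours gave 26 Leiden clusters at resolution 1, without integration (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, matplotlib 3.10.9).

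Clusters were called "-like" from the marker lists. A marker counted where at least 10% of the cluster's cells held it at 2 or more times the level of the other cells, at least 3 were required, and the 10 leading genes by fold were inspected. Endothelial-like clusters were joined into a class, and so were the blood progenitor, macrophage and neutrophil-like clusters, with erythroid-like clusters kept apart. Clusters 3, 17 and 20 stayed unnamed. Cluster 3 had endothelial markers but a median of 2848 UMIs per cell and none of those markers among its leading genes. Cluster 17 had under 3 markers. Cluster 20 had 14 mesenchyme markers raised, but its 10 leading genes held 0 of them and 1 marker of the blood class, fn1b. Cluster 21 kept its name with a median of 2274 UMIs per cell, since 3 endothelial markers were among its leading genes. The unnamed clusters held 6.84% of kept cells in the control libraries and 9.94% in the morphant libraries on average. The blood progenitor-like kind contains cluster 2, whose leading genes include gata1b, zfpm1 and the thrombopoietin receptor gene mpl. It also contains cluster 13, whose best marker list was the lymphoid one, with 7 markers raised and 0 among its leading genes, which include runx3 and s1pr4. Cluster 13 gave 113 of 656 blood progenitor-like cells in control 1, 9 of 132 in control 2, 45 of 359 in morphant 1 and 27 of 179 in morphant 2. The macrophage-like cluster 6 also held skeletal muscle transcripts.

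UMIs were summed per library and class and compared with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) under R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 and a fold of at least 1.5. With no gene changed, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. The counts of such genes given below were near that share except in all cells, the blood progenitor and white cell-like class and the erythroid-like class. Fold changes are morphant over control on the log2 scale, and each standard error is the size of the log2 fold change divided by the square root of F. A class was tested with at least 20 cells in every library, which left out the epidermis, neural and pigment-like clusters. The 23 gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. Lists of cell type markers were tested the same way. The difference between the endothelial and the blood response was tested as a class by treatment interaction with library as a block. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only, and were compared with edgeR on the numbers of cells. CPM values are UMIs scaled to a common total for each class sum.

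The rule for naming genes takes prdx1, the called genes with the largest folds (10 in each direction for the main classes, 5 for other classes), and up to 4 members of each list by adjusted p. A gene taken by its fold needed both morphant libraries beyond both control libraries, a mean of at least 20 CPM in the higher group and a name that is not a clone or locus identifier. Other called genes were named after their values were seen where a class had few calls, as were rps27l and rpl22l1 across classes. A gene and the gene list named after it are not reported here.

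The test was tested on simulated data drawn from the means, library sizes and dispersions of 4 of the sums, in 10 draws with 200 changed genes and 10 draws with none. Changed genes were drawn only from those with an expected count of at least 20 UMIs in the smallest library. Recovery of genes below that level was not measured. Each gene was drawn independently, with a dispersion estimated from the same libraries. A shift shared by many genes in a lane was therefore not simulated. Of genes changed 2-fold, 26.3% were recovered in the all-cell sums over 18395 genes, 64.2% in the endothelial-like class over 11661 genes, 65.2% in the blood progenitor and white cell-like class over 16119 genes and 63.5% in the erythroid-like class over 7605 genes. Of genes changed 4-fold, the shares were 82.5%, 100%, 97.6% and 97.2%. False calls made up 15.7%, 6.12%, 10.1% and 4.00% of all calls in the same order, so the adjusted p understates the false share in the first 3 of these sums, and the other kinds were not simulated. With no gene changed, the mean number of calls per draw was 6.8, 1.6, 3.4 and 0.1, and the highest was 19, 8, 14 and 1.

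The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate number as a block, each library left out in turn, looser and stricter cell filters, doublets kept, libraries thinned to the lowest median depth, haemoglobin genes left out, no fold floor, other clustering resolutions and clustering without the gene called in all cells. Class membership and a crossed block were added after seeing the data.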

Results

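The sorted cells of control and prdx1 morphant embryos were compared in 4 droplet libraries, 2 lanes of 1 cell suspension per condition. Total depth was 60434176 UMIs in control 1, 26953378 in control 2, 47998692 in morphant 1 and 42234662 in morphant 2. After filtering, 3633, 1016, 2885 and 2170 cells remained in the same order, with medians of 13164, 23009, 10417 and 13896 UMIs per cell. Control 2 thus held the fewest cells and the most UMIs per cell, and values for small classes rest on few cells in that lane. Besides endothelial-like cells, the sort held macrophage-like, erythroid-like, blood progenitor-like, neutrophil-like and mesenchyme-like cells.

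The knockdown target was examined in every library. Over all kept cells, prdx1 stood at 163 and 192 CPM in the control libraries and at 148 and 140 CPM in the morphant libraries. The log2 fold change was -0.30 (SE 0.15), which did not pass the test (adjusted p = 0.622, edgeR with Benjamini-Hochberg adjustment). Neutrophil-like cells had the highest level, with 664 and 970 CPM in the controls and 542 and 440 CPM in the morphants, a log2 fold change of -0.73 (SE 0.17, adjusted p = 0.569, edgeR with Benjamini-Hochberg adjustment). In endothelial-like cells the values were 234 and 175 CPM against 261 and 273 CPM, a log2 fold change of 0.37 (SE 0.21, adjusted p = 0.985 by the same edgeR test and Benjamini-Hochberg adjustment). The log2 fold change was -0.38 (SE 0.17) in the joined blood progenitor and white cell-like class, 0.51 (SE 0.20) in erythroid-like cells and -1.02 (SE 0.66) in mesenchyme-like cells. Some of these values moved with a single lane or setting. Leaving out 1 library leaves a single library in a group, so for those fits only the fold is given here. In mesenchyme-like cells the log2 fold change was -1.75 without control 1 and 0.46 without control 2. The level there was 258 CPM in control 2, where 30 of 65 mesenchyme-like cells came from cluster 23, against 54.6 CPM in control 1, where 5 of 153 did. In neutrophil-like cells the log2 fold change was -0.98 without control 1 and -0.89 without morphant 1. It was 0.80 in erythroid-like cells without control 2, and 1.13 in endothelial-like cells outside the venous or lymphatic clusters without control 1. With all 4 libraries and no filter on low counts, prdx1 was called in neutrophil-like cells at -0.71 (adjusted p = 1.4e-05, edgeR with Benjamini-Hochberg adjustment). The fold was close to the -0.73 found with the filter, and this setting raised the number of calls in these cells from 1 to 87. A morpholino that blocks translation need not lower the transcript, and the labels do not state which kind was used.

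**Figure D1:**
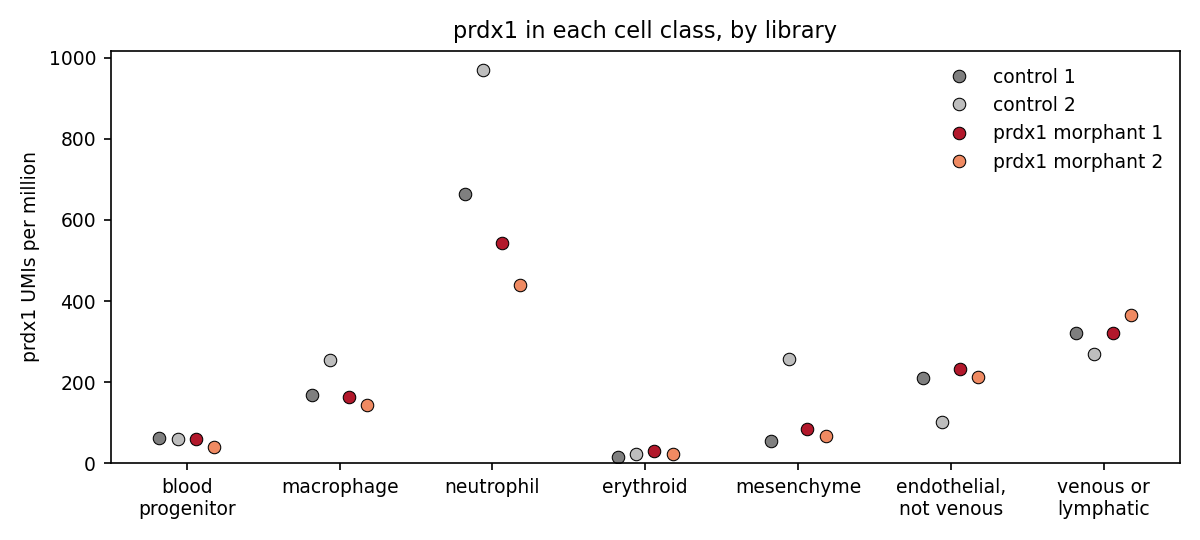
CPM of prdx1 (vertical axis) in each of 7 cell kinds (horizontal axis), where each point is the sum over the cells of 1 library. Neutrophil-like cells had the highest values, from 440 to 970 CPM, and the difference between the groups was not called in any of the kinds.

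The composition of the sort was compared next. Venous or lymphatic endothelial-like cells made up 5.15% ± 0.934 (SD, n = 2) of control cells and 11.2% ± 0.328 (SD, n = 2) of morphant cells, a log2 fold change of 1.12 (SE 0.43). This kind joins clusters 7 and 21, with medians of 6817 and 2274 UMIs per cell. Cluster 7 held 2.09% of control and 4.91% of morphant cells, and cluster 21 held 3.06% and 6.24%. The kind gave no value under the stricter cell filter. Erythroid-like cells made up 23.7% ± 6.78 against 11.8% ± 1.13 (SD, n = 2 each), a log2 fold change of -1.003 (SE 0.45). Blood progenitor-like cells made up 15.5% ± 3.58 against 10.3% ± 2.97, with a log2 fold change of -0.59 (SE 0.46). Macrophage-like cells were the most frequent kind by group mean, at 24.8% ± 5.65 and 29.3% ± 0.495, and neutrophil-like cells stood at 10.4% ± 1.32 and 10.5% ± 2.03. In control 2 alone, erythroid-like cells were more frequent than macrophage-like cells, with 28.4% against 20.8%. In each of these kinds except the neutrophil-like cells, both morphant libraries lay on the same side of both control libraries.

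None of the differences in share passed the test. Of 11 classes, 0 were called by edgeR with Benjamini-Hochberg adjustment, and 1, the venous or lymphatic endothelial-like cells, had an unadjusted p under 0.05 (adjusted p = 0.293). The classes were not compared with another tool. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333. The lanes of the control suspension differed from each other, with 18.9% erythroid-like cells in control 1 (95% interval 17.6 to 20.2%, Clopper-Pearson) and 28.4% in control 2 (25.7 to 31.3%). Epidermis-like cells made up 0.385% of control 1 (0.211 to 0.646%) and 2.66% of control 2 (1.76 to 3.84%). These differences exceed counting error, although the labels call the lanes technical replicates, and their source was not tested. Without control 1, 6 classes were called, and without control 2, 5 were.

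**Figure D2:**
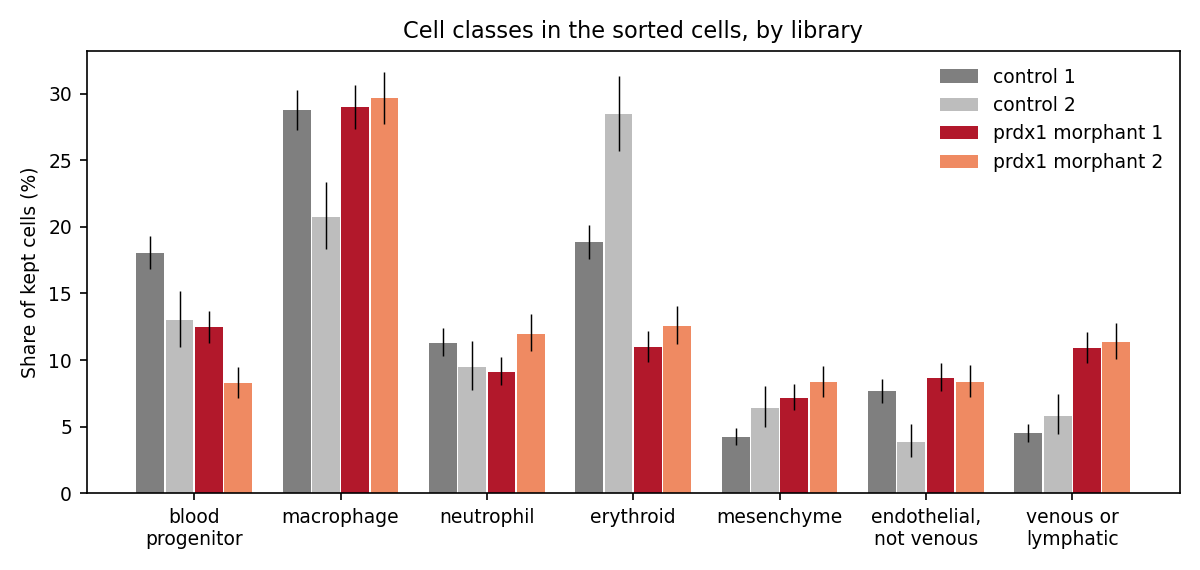
Share of kept cells in percent (vertical axis) for 7 cell kinds (horizontal axis), with a bar for each library and lines for the exact 95% interval of counting error. Venous or lymphatic endothelial-like cells lay at 4.49% and 5.81% in the control libraries and at 10.9% and 11.4% in the morphant libraries.

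In the endothelial-like class, 3 genes rose in the morphant libraries and 0 fell, of 11661 tested. The hyaluronan receptor gene lyve1a, a marker of lymphatic and venous vessels, rose from a mean of 20.3 to 85.5 CPM (log2 fold change 2.03, SE 0.24, adjusted p = 0.0098, edgeR with Benjamini-Hochberg adjustment). The ribosomal protein S27-like gene rps27l rose from 139 to 361 CPM (log2 fold change 1.38, SE 0.20, adjusted p = 0.038, edgeR with Benjamini-Hochberg adjustment). The third gene, si:dkey-40h20.1, named after its values were seen, rose by 3.25 (SE 0.40) on the log2 scale. Within the class, the venous or lymphatic clusters 7 and 21 held more of the morphant cells than cluster 1, with 11.2% against 8.53% of kept cells, while the control lanes differed in direction, with 4.49% against 7.65% in control 1 and 5.81% against 3.84% in control 2. When the kinds were tested apart, lyve1a had log2 fold changes of 1.76 (SE 0.31) in the venous or lymphatic endothelial-like cells and 1.22 (SE 0.43) in the other endothelial-like cells, and it was not called in either. Without control 1 the fold of si:dkey-40h20.1 was 2.26 and without morphant 1 that of rps27l was 1.34, and neither was then called.

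The count of 3 lies within what simulated data with no change gave for this class, 1.6 calls on average and 8 at most. Of 11661 genes tested, 615 had an unadjusted p under 0.05, near the share that no change would give, and DESeq2 called 13. Without control 1, control 2, morphant 1 or morphant 2 the count was 18, 257, 32 and 34, and with doublets kept or with the looser cell filter it was 0. The folds of lyve1a and rps27l were then 1.98 and 1.38 with doublets kept (adjusted p = 0.0671 and 0.0869) and 1.95 and 1.296 with the looser filter (adjusted p = 0.0766 and 0.0847). Of the 3 calls, 1 was shared with resolution 0.5, 2 with resolution 2.0 and 2 with cluster 3 joined to the class.

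In the endothelial-like class camera called 6 of 23 lists at its preset correlation, 2 upward and 4 downward, and 0 with an estimated correlation. The adjusted p of the 6 lists was then 0.501 for the hypoxia, arterial, haemogenic and erythroid lists and 0.814 for both mitochondrial lists, and fry called 0. Venous or lymphatic endothelial-like cells made up 5.15% of control and 11.2% of morphant cells on average, and the other endothelial-like cells 5.75% and 8.53%. For all lists and markers in this class, a shift in this mix was not separated from changes within cells. At the preset correlation the lists behaved as follows. Hypoxia and glycolysis genes shifted upward, with 23 of 29 members positive (camera adjusted p = 3.0e-05 with Benjamini-Hochberg adjustment), and 3 rose and 0 fell when adjusted over the list alone. The glycolytic enzyme genes eno1a and ldha had log2 fold changes of 2.26 (SE 0.38) and 1.203 (SE 0.28), and epas1b, which encodes a hypoxia-inducible factor, 1.07 (SE 0.29). Nuclear genes of oxidative phosphorylation shifted upward, with 36 of 41 positive and a median log2 fold change of 0.17 (camera adjusted p = 0.000224), while 12 of 13 genes of the mitochondrial genome were negative, with a median of -0.14 (camera adjusted p = 0.0261, both with Benjamini-Hochberg adjustment). In both lists 0 members passed edgeR's test when adjusted over the list alone, with 13 of the mitochondrial and 41 of the nuclear genes tested. The arterial identity and Notch list shifted downward, with 12 of 16 members negative (camera adjusted p = 0.00723 with Benjamini-Hochberg adjustment) and 1 that fell when adjusted over the list alone. Among its members were the chemokine receptor gene cxcr4a (-1.49, SE 0.26), the arterial ligand gene efnb2a (-0.54, SE 0.20) and the Notch target hey2 (-0.74, SE 0.29), while unc5b was positive (0.76, SE 0.31). The haemogenic endothelium and blood stem cell list also shifted downward, with 9 of 11 negative (camera adjusted p = 0.000224 with Benjamini-Hochberg adjustment) and 1 that fell when adjusted over the list alone, the receptor gene kita (-0.92, SE 0.21). The transcription factor gene runx1 stood at -0.97 (SE 0.56). Among cell type markers, 10 of 13 venous or lymphatic markers were positive (camera adjusted p = 0.0023) and 8 of 9 arterial markers negative (camera adjusted p = 0.00764, both with Benjamini-Hochberg adjustment, and 0.462 and 0.428 as adjusted p with an estimated correlation).

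The erythroid and haem list had the lowest camera p, with 16 of 21 members negative (adjusted p = 1.6e-13, camera with Benjamini-Hochberg adjustment) and 13 that fell when adjusted over the list alone. The carbonic anhydrase gene cahz stood at 25.5 and 7.24 CPM in the controls and 2.72 and 3.75 CPM in the morphants. Of the erythroid markers, 14 of 15 were negative. Without control 1, the log2 fold change of slc4a1a in this class went from -2.47 to 0.28. With an estimated correlation the adjusted p of the erythroid list was 0.501. Of 15 peroxiredoxin and thioredoxin genes 9 were positive (camera adjusted p = 0.355), and of 21 antioxidant and Nrf2 target genes 10 were (camera adjusted p = 0.907, both with Benjamini-Hochberg adjustment). Without control 2, 11 lists were called.

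In the endothelial-like cells outside the venous or lymphatic clusters, 7 genes rose and 8 fell of 10336 tested. The gene phlda3 rose from 0.873 to 28.6 CPM (log2 fold change 4.21, SE 0.56), the enolase gene eno1a from 3.79 to 28.4 CPM (2.63, SE 0.45) and rps27l from 89.9 to 373 CPM (1.93, SE 0.32), with adjusted p of 0.00281, 0.0203 and 0.0166 by edgeR with Benjamini-Hochberg adjustment. The link protein gene hapln1a fell by 2.17 on the log2 scale (SE 0.35), from 39.4 to 8.80 CPM, and was named after its values were seen. The other 7 genes that fell are red cell genes, such as the globin genes hbbe1.1 (-3.81, SE 0.73) and hbbe2 (-3.59, SE 0.61), the anion exchanger gene slc4a1a (-3.71, SE 0.56) and cahz (-3.33, SE 0.52). The fall of the 5 globin genes among them rests on control 1, in which haemoglobin genes made up 19983 CPM of these cells, against 1485 CPM in control 2 and 1151 and 1059 CPM in the morphants. Without control 1 the log2 fold change of hbbe1.1 was -0.36 and that of hbbe2 -0.27, neither of them called, and without control 2 they were -4.73 and -4.33. For slc4a1a control 1 stood at 33.6 and control 2 at 5.55 CPM, against 2.31 and 1.51 CPM in the morphants, and for cahz the values were 30.1, 8.32, 3.08 and 1.51 CPM. Neither gene was tested without control 1.

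Control 2 held no UMI of phlda3 in these cells. Without control 1 the folds of phlda3, eno1a and rps27l were 8.58, 3.31 and 2.84. With the looser cell filter, the stricter cell filter and resolution 0.5 that of phlda3 was 3.13, 3.02 and 2.24 (adjusted p = 0.223, 0.128 and 0.462), and that of eno1a 2.20, 2.64 and 2.05, none of them called. DESeq2 gave eno1a a fold of 2.72 and an adjusted p of 0.265. Of the 15 calls, 4 were shared with DESeq2, 1 with the looser filter, 2 with the stricter filter, 2 with doublets kept and 0 with resolution 0.5. Without morphant 2 the folds of eno1a and hapln1a were 2.30 and -1.80, neither of them called. DESeq2 called 6 genes, 453 had an unadjusted p under 0.05, and leaving out control 1, control 2, morphant 1 or morphant 2 gave 495, 131, 23 and 17 calls. Control 2 contributed 39 of these cells. In the venous or lymphatic endothelial-like cells 1 gene of 8335 fell by edgeR and 0 rose, 367 had an unadjusted p under 0.05 and DESeq2 called 3. It was rpl22l1, which encodes a paralog of ribosomal protein L22 and fell by 1.35 (SE 0.18, adjusted p = 0.0207, edgeR with Benjamini-Hochberg adjustment) on the log2 scale, from 1159 to 456 CPM. Counts for these cells were 89, 78, 10 and 4 with the same libraries left out, and 0 with the looser cell filter and with no filter on low counts, where rpl22l1 stood at -1.37 and -1.25. Without morphant 2 the log2 fold change of rpl22l1 was -1.21 and not called. All 10 erythroid markers tested in these cells were negative, with a median of -1.05. Haemoglobin genes stood at 6091 CPM in control 1 but at 2130 CPM in control 2, between the morphants at 2305 and 1665 CPM, so their fall rests on control 1.

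In the blood progenitor and white cell-like class, 4 genes rose and 1 fell of 16119 tested. The cholesterol 25-hydroxylase gene ch25h rose from 29.3 to 87.5 CPM (log2 fold change 1.58, SE 0.16, adjusted p = 0.00492, edgeR with Benjamini-Hochberg adjustment), and slc4a1a, the anion exchanger of red cells, fell from 28.3 to 9.60 CPM (log2 fold change -1.55, SE 0.17, adjusted p = 0.00876, edgeR with Benjamini-Hochberg adjustment). The other 3 were low in expression and were named after their values were seen. They are CR352342.1, with a log2 fold change of 3.06 (SE 0.18), the carboxypeptidase gene cpn1|ENSDARG00000096728, with 3.63 (SE 0.31), and ghrh, with 2.57 (SE 0.30). With the looser cell filter, the stricter cell filter and doublets kept, slc4a1a had log2 fold changes of -0.60, -1.41 and -1.43 and was not called (adjusted p = 0.334, 0.429 and 0.0689). Of the 5 calls, 4, 3 and 4 were shared with these settings in turn, and 1 with the replicate number as a block. Without control 1 the fold of cpn1|ENSDARG00000096728 was 3.02. The count of 5 lies within what simulated data with no change gave, 3.4 calls on average and 14 at most, while 1401 genes had an unadjusted p under 0.05 and DESeq2 called 114. Without control 1, control 2, morphant 1 or morphant 2 there were 659, 217, 338 and 24 calls.

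Camera called 11 of 23 lists in this class at its preset correlation, 7 upward and 4 downward, but 0 with an estimated correlation, and fry called 0. For the upward lists named here, the adjusted p with an estimated correlation lay between 0.365 (inflammation and interferon) and 0.572 (macrophage and neutrophil). At the preset correlation the upward lists were as follows. Immediate early genes, which also respond to tissue dissociation, shifted upward with 23 of 24 members positive (adjusted p = 9.6e-16, camera with Benjamini-Hochberg adjustment) and 10 that rose when adjusted over the list alone, among them fosb (log2 fold change 1.04, SE 0.20) and egr1 (0.89, SE 0.20). Inflammation and interferon genes shifted upward with 26 of 29 positive (adjusted p = 2.2e-09, camera with Benjamini-Hochberg adjustment), including the neutrophil attractant gene cxcl8a (1.22, SE 0.25), the cytokine gene tnfb (0.74, SE 0.16) and the acute phase gene saa (1.22, SE 0.22). When adjusted over the list alone, 4 of the inflammation genes rose. Further upward shifts were found for BMP, Wnt and TGF-beta targets (15 of 18 positive, id1 at 0.92, SE 0.35), extracellular matrix genes (17 of 23), macrophage and neutrophil genes (18 of 20, mpeg1.1 at 0.59, SE 0.22) and hypoxia and glycolysis genes (23 of 34, eno1a at 0.84, SE 0.25, but hif1aa at -1.20, SE 0.36), with camera adjusted p of 0.000274, 0.00156, 0.00108 and 0.0271 after Benjamini-Hochberg adjustment. Of these lists, 1 BMP, Wnt or TGF-beta target and 0 members of the others rose when adjusted over the list alone. Of 16 peroxiredoxin and thioredoxin genes, 10 were positive (adjusted p = 0.911, camera with Benjamini-Hochberg adjustment).

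Downward shifts in this class, at the preset correlation alone, covered red cell, stem cell and proliferation genes. The erythroid and haem list had 27 of 29 members negative (adjusted p = 1.4e-26, camera with Benjamini-Hochberg adjustment), with 14 that fell when adjusted over the list alone. In macrophage-like cells of control 1, control 2 and morphant 2, 5% of the cells held most of the haemoglobin UMIs. The haemogenic endothelium and blood stem cell list had 14 of 18 negative, with 4 that fell when adjusted over the list alone, and included gfi1b (-1.60, SE 0.27), tal1 (-1.13, SE 0.27) and lmo2 (-0.69, SE 0.22), which encode transcription regulators of early blood cells. DNA repair genes had 24 of 26 negative, including lig1 (-0.59, SE 0.15), and cell cycle genes 28 of 38, including stmn1a (-0.60, SE 0.16) and pcna (-0.38, SE 0.15) but not birc5a (0.34, SE 0.15). When adjusted over the list alone, 0 of either fell. Camera adjusted p for these 3 lists were 3.0e-06, 2.0e-05 and 0.00292 with Benjamini-Hochberg adjustment. Blood progenitor-like cells gave 656 of 2112 cells of the class in control 1 and 132 of 439 in control 2. In morphant 1 and morphant 2 they gave 359 of 1458 and 179 of 1083. For the upward and downward lists alike, a shift in this mix was not separated from changes within cells. Cluster 2, the part of the class with erythroid and thrombocyte leading genes, held 6.27% of control cells and 3.34% of morphant cells, and all 5 thrombocyte markers tested in the class were negative (median -1.38). Skeletal muscle markers were negative as well, in 16 of 17 (median -1.70). None of the 11 calls held with an estimated correlation, with an adjusted p from 0.230 for the erythroid list to 0.572 for the macrophage and neutrophil list, and fry called 0.

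The kinds within the blood class were tested apart. In macrophage-like cells 6 genes rose and 1 fell of 13154 tested, with cpn1|ENSDARG00000096728 at a log2 fold change of 3.998 (SE 0.33), phlda2, a relative of phlda3, at 2.84 (SE 0.32) and rps27l at 1.23 (SE 0.14), while rpl22l1 fell by 1.32 (SE 0.13), from 940 to 376 CPM. Their adjusted p were 0.0151, 0.0402, 0.0402 and 0.0292 by edgeR with Benjamini-Hochberg adjustment. In neutrophil-like cells rpl22l1 was the gene called of 10143 tested, and it fell by 1.33 (SE 0.13, adjusted p = 0.0103, edgeR with Benjamini-Hochberg adjustment), from 605 to 241 CPM. In blood progenitor-like cells 1 gene of 12654 fell, CABZ01058647.1, by 5.36 (SE 0.52) on the log2 scale, from 7.49 to 0.198 CPM, and was named after its values were seen. It was not among the 32 genes that DESeq2 called in these cells, where its fold was -5.45, and by edgeR its fold was -4.52 without morphant 1 and -6.26 without morphant 2. CABZ01058647.1 is also a leading gene of the neutrophil-like cluster 12, and its log2 fold change in neutrophil-like cells was 0.38 (SE 0.33). Unadjusted p were under 0.05 for 498 genes in macrophage-like, 564 in neutrophil-like and 660 in blood progenitor-like cells, and DESeq2 called 17, 2 and 32. Without control 1, control 2, morphant 1 or morphant 2 the counts were 77, 28, 11 and 2 in macrophage-like cells, 54, 64, 76 and 33 in neutrophil-like cells, and 75, 44, 38 and 142 in blood progenitor-like cells. In macrophage-like cells the folds of cpn1|ENSDARG00000096728, phlda2, rps27l and rpl22l1 were 3.97, 2.65, 1.33 and -1.46 without morphant 2, and that of rps27l 1.11 without morphant 1, none of them called. Without control 1 those of cpn1|ENSDARG00000096728 and phlda2 were 3.25 and 3.67. With the replicate number as a block, 1 of the 7 calls in macrophage-like cells was shared, and cpn1|ENSDARG00000096728, phlda2, rps27l and rpl22l1 stood at 3.95, 2.85, 1.22 and -1.33 (adjusted p = 0.116, 0.254, 0.254 and 0.179). In neutrophil-like cells rpl22l1 then stood at -1.33 and was not called (adjusted p = 0.20). Erythroid markers were negative in 19 of 19 in macrophage-like, 14 of 15 in neutrophil-like and 21 of 21 in blood progenitor-like cells, and 16 of 17 skeletal muscle markers in macrophage-like cells. In neutrophil-like cells the fall of the haemoglobin genes rests on control 1, with 6046 CPM, against 574 CPM in control 2 and 744 and 542 CPM in the morphants. In macrophage-like cells they stood at 12733 and 6150 CPM against 1212 and 3790 CPM, and in blood progenitor-like cells at 3354 and 1753 against 1389 and 956 CPM. The 5% of macrophage-like cells with most haemoglobin UMIs held 86.3% and 88.6% of them in the controls and 14.6% and 84.2% in the morphants. The median macrophage-like cell stood at 2246 and 855 CPM in the controls and 1282 and 734 CPM in the morphants.

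In erythroid-like cells edgeR called 155 genes that rose and 30 that fell of 7605 tested. The 5 genes in each direction that the naming rule takes are given here. The nucleophosmin gene npm1a rose from 5.45 to 27.4 CPM (log2 fold change 2.32, SE 0.23), nop58 and nop56, which encode core proteins of box C/D ribonucleoproteins, by 2.11 (SE 0.22) and 1.62 (SE 0.28), the nucleolin gene ncl by 1.39 (SE 0.20) and the chaperone gene pfdn4 by 1.13 (SE 0.19). Among the genes that fell, rpl22l1 went from 323 to 115 CPM (log2 fold change -1.49, SE 0.17), a pair of histone H4 copies, hist1h4l|ENSDARG00000111247 and hist1h4l|ENSDARG00000105382, fell by 1.23 (SE 0.27) and 1.07 (SE 0.18), rnf10 by 0.94 (SE 0.19) and ccni by 0.89 (SE 0.18). Reads shared between the histone copies cannot be assigned with certainty. Adjusted p ranged from 0.000205 for npm1a to 0.0243 for the first histone copy by edgeR with Benjamini-Hochberg adjustment.

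Of the fixed lists, 73 of 74 cytosolic ribosome genes were negative in erythroid-like cells, with a median log2 fold change of -0.27 (adjusted p = 1.9e-11, camera with Benjamini-Hochberg adjustment), and 13 of 13 genes of the mitochondrial genome were negative, with a median of -0.42. Cell cycle genes shifted upward, with 31 of 37 positive (adjusted p = 0.00058, camera with Benjamini-Hochberg adjustment). When adjusted over the list alone, 5 cell cycle genes rose, 4 mitochondrial genes fell and 0 ribosome genes fell. None of these lists was called with an estimated correlation (adjusted p = 0.682). Haemoglobin genes made up 83.5%, 85.5%, 83.9% and 82.4% of the UMIs in control 1, control 2, morphant 1 and morphant 2. The largest number of calls in a simulation with no change was 1. That simulation drew each gene independently, so it cannot hold a shift shared by many genes in a lane and does not exclude one. When the called doublets were kept, edgeR called 0 genes, with 682 at an unadjusted p under 0.05 against 1173, and the fold of npm1a was 1.60. The stricter cell filter gave 5 calls, and npm1a was not called at a fold of 2.13 (adjusted p = 0.119). All 176 of the called genes still tested then had the same sign, with a median ratio of folds of 0.908. Of 206 genes mainly expressed in the blood class, 162 were positive in these cells (median 0.49). Without morphant 1 the fold of hist1h4l|ENSDARG00000111247 was -0.86, and without morphant 2 those of rnf10 and ccni were -0.88 and -0.77, none of them called. Without morphant 2 that of hist1h4l|ENSDARG00000111247 was -1.84. DESeq2 called 67, the libraries thinned to the lowest depth gave 93, and without control 1, control 2, morphant 1 or morphant 2 there were 306, 343, 197 and 138 calls.

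In mesenchyme-like cells edgeR called 0 genes of 9686, with 479 at an unadjusted p under 0.05 and 7 called by DESeq2. Without control 1, control 2, morphant 1 or morphant 2 the counts were 695, 116, 4 and 0. The class was made up differently in 1 control lane, since cluster 23, led by and2 and and1, gave 30 of 65 mesenchyme-like cells in control 2 but 5 of 153, 5 of 207 and 2 of 181 in control 1, morphant 1 and morphant 2. All 35 cell cycle genes tested in mesenchyme-like cells were positive (median 0.67, camera adjusted p = 1.1e-09 with Benjamini-Hochberg adjustment, adjusted p = 0.964 with an estimated correlation), and 0 rose by edgeR when adjusted over the list alone. All 16 mesenchyme markers and all 9 erythroid markers were negative there, with haemoglobin genes at 3588 CPM in control 1 and 1023 CPM in control 2, against 1566 and 1008 CPM in the morphants, so that their fall rests on control 1. Cluster 3, which had endothelial markers and few UMIs, gave 0 of 3433 by edgeR, 166 at an unadjusted p under 0.05, 3 by DESeq2, and 124, 53, 0 and 0 with the same libraries left out. Over all kept cells 1 gene of 18395 rose, CR352342.1, from 1.92 to 15.4 CPM (log2 fold change 2.995, SE 0.16, adjusted p = 0.0424, edgeR with Benjamini-Hochberg adjustment). Simulated data with no change gave 6.8 calls on average and 19 at most in these sums, 1740 genes had an unadjusted p under 0.05, DESeq2 called 321, and the same libraries left out gave 2099, 548, 0 and 0, so that CR352342.1 was not called without either morphant library, at folds of 2.9996 and 2.9947. It was also not called with the replicate number as a block (2.9963, adjusted p = 0.426), the looser cell filter (2.96, adjusted p = 0.0512) and the stricter one (2.91, adjusted p = 0.0535).

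A search over the 5349 genes tested in all 7 named kinds of cells found 1 gene, FO704772.3, with a fold of at least 1.5 in the same direction in every kind, downward. The split of control 1 and morphant 2 against control 2 and morphant 1 also gave 1 such gene, and the split by replicate number 0, so the count of 1 is no more than a split without the treatment gave. The log2 fold change of rpl22l1 was negative in 7 of 7, from -1.53 to -0.46 with a median of -1.33, and it was called in 4. That of rps27l was positive in 7 of 7, from 0.18 to 1.93, and was called in 2. The paralog rpl22 had 5 positive and 2 negative values, from -0.20 to 0.15, and was not called in any kind. All 4 genes were singled out after their values were seen.

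**Figure D3:**
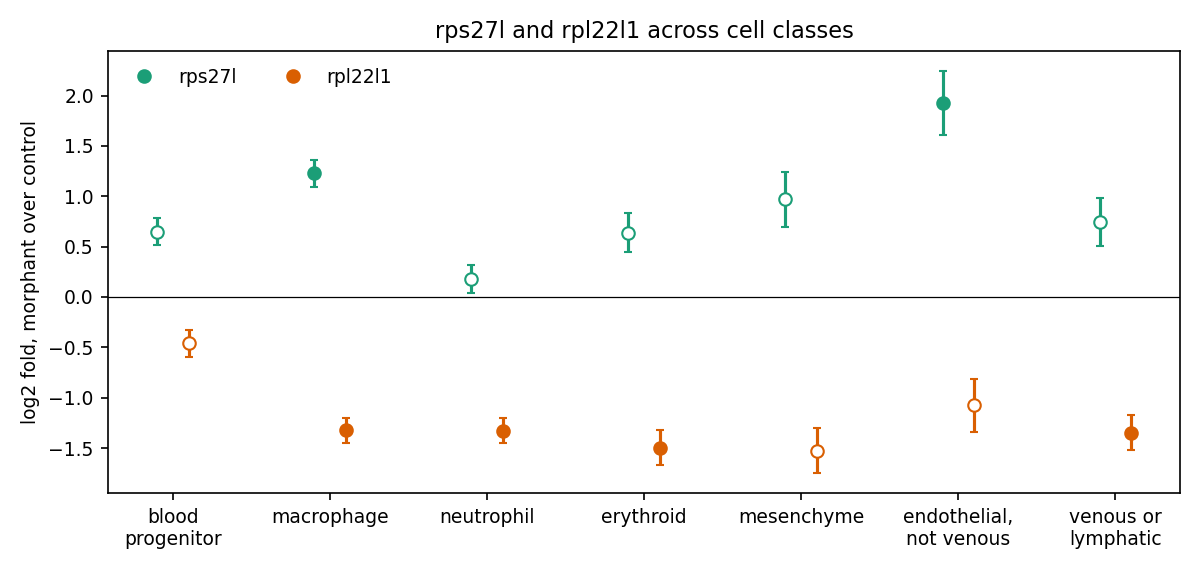
Log2 fold change of morphant over control libraries (vertical axis) for rps27l and rpl22l1 in each of 7 cell kinds (horizontal axis), with filled circles for called genes, open circles for genes not called and bars for the standard error. The values of rpl22l1 lie between -1.53 and -0.46 and those of rps27l between 0.18 and 1.93.

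The difference between the endothelial and the blood response was tested directly, and edgeR with Benjamini-Hochberg adjustment called 8 of 15548 genes, with 836 at an unadjusted p under 0.05. The arterial chemokine receptor gene cxcr4a had log2 fold changes of -1.49 in endothelial-like cells and 0.35 in the blood class (difference -1.85, SE 0.35, adjusted p = 0.0428), and the thrombopoietin receptor gene mpl 1.11 and -1.08 (difference 2.04, SE 0.37, adjusted p = 0.0267). Cluster 2 of the blood class, where mpl is a leading gene, held 6.27% of control cells and 3.34% of morphant cells. Each class joins several clusters, and a shift in their mix was not separated from a change within cells. The differences for rps27l (0.35, SE 0.23), rpl22l1 (-0.29, SE 0.20) and prdx1 (0.72, SE 0.26) did not pass the test. Without control 2, 4 genes were called, and without morphant 1, 31 were.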

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

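The genes below were picked out because their response differed between endothelial-like cells and the blood progenitor and white cell-like class in the test of the difference itself (edgeR class by treatment interaction), and no test here was chosen after the result was seen. Differences are endothelial minus blood log2 fold changes of morphant over control libraries. Each class joins several clusters, and a shift in their mix was not separated from a change within cells. That of cxcr4a was -1.85, with -1.49 in endothelial-like cells and 0.35 in the blood class. That of the thrombopoietin receptor gene mpl was 2.04, with 1.11 and -1.08. Cluster 2 of the blood class, where mpl is a leading gene, held 6.27% of control and 3.34% of morphant cells. The difference for serpinh1b, which encodes a collagen chaperone, was -1.71, with -0.52 and 1.11. That of nanos1 was -1.80, with -1.12 and 0.63. That of zgc:66433 was 1.55, with -0.00 and -1.59. That of si:dkey-85k7.7 was 2.90, with 1.91 and -0.84. That of CABZ01030107.1 was -3.31, with -1.22 and 2.08. That of si:ch211-103n10.5 was -6.16, with 0.42 in the blood class and no test in endothelial-like cells, where it did not pass the filter on low counts. Without control 2, 4 genes were called, and without morphant 1, 31 were.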

How the results depend on the processing

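The joining of cluster 3 to the endothelial-like cells, the removal of the macrophage-like cluster with muscle genes and the crossed block were chosen after the results were seen. Over all alternatives to the values reported, 2068 values kept their direction and their side of the threshold, 222 newly passed it, 172 no longer did, 124 moved and 9 reversed. The 2068 include 138 values with no fold floor and 141 from clustering without the gene called in all cells. These settings left every set of called genes unchanged and say little about stability. Counts of called genes were among the values that moved, and the cause was not tested except where fewer libraries, genes or cells entered by construction. Each group is 2 lanes, and control 2, with 1016 cells in all, entered the small kinds with few cells.

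DESeq2 called 321 genes in all cells, 13 in endothelial-like cells, 114 in the blood progenitor and white cell-like class, 67 in erythroid-like, 7 in mesenchyme-like, 32 in blood progenitor-like, 17 in macrophage-like and 2 in neutrophil-like cells, 6 in endothelial-like cells outside the venous or lymphatic clusters, 3 in venous or lymphatic endothelial-like cells, 3 in cluster 3 and 123 over all classes besides the endothelial and joined blood classes. With RLE factors the count in endothelial-like cells outside the venous or lymphatic clusters was 9, and it was also 9 without haemoglobin genes. With no filter on low counts the counts were 73 in endothelial-like cells, 508 in the blood class, 323 in erythroid-like, 234 in mesenchyme-like, 230 in blood progenitor-like, 172 in macrophage-like and 87 in neutrophil-like cells, 50 in endothelial-like cells outside the venous or lymphatic clusters, 0 in venous or lymphatic endothelial-like cells by edgeR, 160 in cluster 3, 1102 over the other classes and 70 for the difference in response.

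The replicate numbers name lanes and do not pair them. Same-numbered deviations had correlations across genes from -0.230 to 0.116, and genes are not independent replicates. With the replicate number as a block the counts were 0 in all cells, 37 in endothelial-like cells, 1 in the blood class, 328 in erythroid-like, 2 in blood progenitor-like, 1 in macrophage-like and 0 in neutrophil-like cells, 50 in endothelial-like cells outside the venous or lymphatic clusters, 3 in venous or lymphatic endothelial-like cells, 31 in cluster 3 and 393 over the other classes. The crossed block gave 398 in the blood class, 40 in mesenchyme-like and 13 in macrophage-like cells.

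With the looser cell filter the counts were 0 in all cells, 0 in endothelial-like, 99 in erythroid-like, 3 in blood progenitor-like and 19 in macrophage-like cells, 1 in endothelial-like cells outside the venous or lymphatic clusters, 0 in venous or lymphatic endothelial-like cells and 118 over the other classes. With the stricter filter they were 0 in all cells, 3 in the blood class, 5 in erythroid-like, 5 in blood progenitor-like and 18 in macrophage-like cells, 3 in endothelial-like cells outside the venous or lymphatic clusters and 26 over the other classes. With doublets kept they were 0 in endothelial-like cells, 10 in the blood class, 0 in erythroid-like, 7 in blood progenitor-like and 17 in macrophage-like cells, 5 in endothelial-like cells outside the venous or lymphatic clusters and 25 over the other classes. The log2 fold change of the neutrophil-like share was -0.0294, -0.0467 and -0.00348 under these 3 settings, and that of the mesenchyme-like share -0.12 with the stricter filter. With libraries thinned to 1 depth the counts were 31 in endothelial-like, 93 in erythroid-like and 5 in blood progenitor-like cells, 0 in venous or lymphatic endothelial-like cells, 110 over the other classes and 47 for the difference in response. At resolution 0.5 the count was 1 in endothelial-like cells and 1 in those outside the venous or lymphatic clusters, and at resolution 2.0 it was 62 in the blood class and 6 in blood progenitor-like cells. With cluster 3 joined, it was 3 in endothelial-like cells outside the venous or lymphatic clusters, and without the cluster with muscle genes it was 55 in the blood class. Camera with an estimated correlation called 0 lists and fry 0 lists in both classes, against 6 and 11.

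Leaving out 1 library leaves a group with a single library, which is then assumed to vary like the other group. The counts then ranged from 0 to 2099 in all cells, 18 to 257 in endothelial-like cells, 24 to 659 in the blood class, 138 to 343 in erythroid-like, 0 to 695 in mesenchyme-like, 38 to 142 in blood progenitor-like, 2 to 77 in macrophage-like and 33 to 76 in neutrophil-like cells, 17 to 495 in endothelial-like cells outside the venous or lymphatic clusters, 4 to 89 in venous or lymphatic endothelial-like cells, 0 to 124 in cluster 3 and 299 to 1691 over the other classes. They ranged from 5 to 11 for endothelial lists, 4 to 31 for the difference in response and 0 to 6 for class shares. Log2 fold changes ranged from -0.19 to 0.21 for the neutrophil-like share, -2.95 to 0.28 for slc4a1a and -0.507 to 0.0399 for mt-nd3 in endothelial-like cells, and -1.75 to 0.46 for prdx1 in mesenchyme-like cells. Cluster 3 gave no value under other cell filters, kept doublets or other clusterings, the venous or lymphatic endothelial-like cells gave none under the stricter filter or resolution 0.5, and the sums over all cells do not depend on the clustering.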

Other observations

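The test of scaling between libraries and the use of the concentration of haemoglobin UMIs against free RNA were chosen after the results were seen. The reporter transcript itself was counted. In venous or lymphatic endothelial-like cells mCherry stood at a mean of 1077 CPM in control and 915 CPM in morphant libraries, and in the other endothelial-like cells at 102 and 91.3 CPM. In blood progenitor-like cells it stood at 2.60 and 0.703 CPM.

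Haemoglobin genes were lower in the morphant endothelial-like cells outside the venous or lymphatic clusters because control 1 held more of them. The 5% of those cells with most haemoglobin UMIs held 88.45% of its haemoglobin UMIs, so a few cells that carried red cell RNA, such as doublets or cells with attached red cells, may account for much of the difference. They do not set the median given below. Free RNA at a like level in every cell met the ratio set for it beforehand, with 1.569 times the highest level of 3 other kinds. Free RNA alone cannot place most UMIs in so few cells, but it may contribute. The median of these cells was 2647 CPM in control 1 and 1632 CPM in control 2, against 1132 and 1166 CPM in the morphants. In venous or lymphatic endothelial-like cells the medians were 6496 and 2353 CPM against 2782 and 2127 CPM. The top 5% of those cells held 15.4% of haemoglobin UMIs in control 1. No biological explanation of this pattern was tested.

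In all 7 kinds rps27l had positive and rpl22l1 negative log2 fold changes. Scaling between libraries moves all genes of a sum alike, so these opposite signs argue against it as the cause of both. The median fold of the cytosolic ribosome list was -0.008614 times that of rpl22l1. This adds little, since TMM factors already centre most genes. Reads shared with the paralog are argued against by the median log2 fold change of rpl22, 0.04989. A response to the loss of prdx1 and a response to morpholino injection itself may each be a source, and neither was tested against the other. Each condition was 1 suspension, so clutch, injection or handling cannot be told apart from the knockdown.

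The erythroid-like cells gave 185 called genes, and a different mix of the 3 erythroid-like clusters is argued against as the whole cause by the median ratio of the fold within clusters to the fold in the class, 0.8577. Tested apart, clusters 4, 16 and 18 gave 0, 47 and 12 called genes by edgeR. RNA of other cells in the erythroid-like cells may contribute and stays open, since the 206 genes at least 50 times higher in the blood class had a median log2 fold change of 0.4857 (95% bootstrap interval 0.392 to 0.605), between the bounds set beforehand. With doublets kept, 177 of the 179 called genes still tested had the same sign, with a median ratio of folds of 0.854, and edgeR called 0. A change within the erythroid cells after the knockdown was not tested apart from these.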
